A study of Mus musculus with 9 samples.

How the data were processed

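RNA was extracted with Trizol from about 20 mg of gastrocnemius of 12-week-old female NSG mice, mRNA was purified with poly-T beads, and libraries were made with Illumina protocols at Novogene, per the labels' protocols. The gene counts are those the authors deposited, as whole numbers per gene and mouse on the mm10 build. The FPKM values were also deposited by the authors, and each equals the count divided by the gene length and by the sum of the library's counts, in FPKM's usual units, within 0.1% for 100% of 161066 values compared, so they carry no scaling factor between libraries. TopHat, STAR 2.5, HTSeq 0.6.1, DESeq2 and edgeR are named without their roles, per the submitters' processing notes. Whether counting used strand, and which annotation release was used, is not stated, so genes that overlap on opposite strands cannot be told apart. Gene symbols and coordinates are those of the deposited table, except that 27 symbols turned into dates by a spreadsheet were restored from the gene ID.

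The 9 libraries formed 2 groups by the EVs injected, with each numbered replicate taken as 1 mouse, since pooling is not mentioned in the labels. Total counts ranged from 13943465 to 25195826 per library, and TMM factors were 0.910, 0.923, 0.985, 0.979 for MCF-10A EV and 1.03, 1.06, 1.02, 1.05, 1.05 for MDA-MB-231 EV. Counts were tested with the quasi-likelihood F-test of edgeR 4.0.16 (robust dispersion, TMM scaling, group as the term, two-sided) in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total count 15). Genes with a Benjamini-Hochberg adjusted p under 0.05 counted as passing. Fold changes are log2 of MDA-MB-231 EV over MCF-10A EV. CPM per gene used TMM-scaled library sizes, except where totals or counts are given as such. The biological coefficient of variation was 20.2%.

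Gene lists for pathways and cell types were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation of 0.01, two-sided), over lists with at least 5 tested members. The same lists were tested with an estimated correlation, with fry, and by an exact permutation of the mean log2 CPM per list. Up to 4 members with the smallest p are named for each list described. Of single genes, up to 15 per direction that passed were to be named, or the 5 with the smallest p where fewer than 5 passed, leaving out predicted and unnamed genes. A fixed set of 19 muscle genes is named whatever its values. The comparison, its test, the lists, the rule for named genes and most alternative settings were chosen before the data were examined.

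The alternative settings chosen then were RLE and upper-quartile factors, unscaled library sizes, leaving out the 20 most abundant genes, no count filter, a filter of CPM 1 in 4 libraries, DESeq2 1.42.0, limma voom, edgeR without robust dispersion, limma on log2(FPKM + 1) and log2(FPKM + 0.1), the replicate number as a block, a minimum absolute log2 fold change of 1, and leaving out each library in turn. Chosen after seeing the data were leaving out both MCF-10A EV replicates 1 and 2, voom with sample weights, the slow-fibre score or the presence of islet transcripts as a covariate, only libraries with or without islet transcripts (Ins2 above 10 CPM), and the permutation of list scores. Random regroupings of the libraries numbered 100 for edgeR and 30 for DESeq2, of 126 possible. In simulated counts of the 13901 tested genes with 200 changed genes, edgeR recovered 34.3%, 67.2% and 92.4% of genes changed 1.5-, 2- and 4-fold with 5.84% false calls, DESeq2 47.8%, 76.1% and 98.5% with 11.4%, and voom 32.8%, 67.2% and 92.4% with 5.88%. The simulated genes varied independently and no library was made to lie apart, so these rates may not hold for the real libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No per-sample column of the files was left out.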

Results

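Poly-A RNA was sequenced from the gastrocnemius, a calf muscle made up mostly of fast-contracting fibres, of female NSG mice, an immunodeficient strain that lacks mature lymphocytes. The mice had been injected through the tail vein with extracellular vesicles (EVs), membrane-bound particles that cells release, at about 10 µg per injection and 2 injections per week for 5 weeks. Muscle was taken 2 days after the last injection. The EVs came either from MCF-10A, a non-tumorigenic line of human breast epithelium (4 libraries, called MCF-10A EV), or from MDA-MB-231, a human breast cancer line (5 libraries, called MDA-MB-231 EV). Total gene counts were 19984136, 13943465, 25195826 and 19474149 for MCF-10A EV replicates 1 to 4, and 24158088, 19934923, 19463570, 19680921 and 20366026 for MDA-MB-231 EV replicates 1 to 5. Of 35275 genes listed, 13901 passed the count filter and were tested. The comparison asks which muscle transcripts differed between mice given EVs of the cancer line and mice given EVs of the non-cancer line. Both groups received EVs, so a difference cannot be assigned to either kind.

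No single gene passed the test, and whether groups of genes passed depended on the list test used. Genes that release and take up calcium, and genes of fast fibres, were lower as lists in MDA-MB-231 EV, with median log2 fold changes of -0.23 and -0.33. Genes of the extracellular matrix, endothelium, mast cells and the cell cycle were higher as lists, with medians of 0.33, 0.36, 0.86 and 0.84. By exact permutation of list means, the unadjusted p was 0.0635 for both matrix and mast cell genes. It was 0.0317 for endothelium, 0.0238 for the cell cycle and 0.00794 for both calcium and fast-fibre genes. The list calls are those of camera with a preset correlation between genes, and none held when the correlation was estimated. The calcium list alone also passed fry's direction test (adjusted p = 0.0128), which presets no correlation. Cish, an inhibitor of cytokine signalling that STAT5 induces, had the smallest p of all genes, with a log2 fold change of -2.58.

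With edgeR's quasi-likelihood test, 0 genes were higher and 0 were lower at a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.133 (Cish). At an unadjusted p under 0.05 there were 1781 genes, 827 higher and 954 lower in MDA-MB-231 EV, where 695 are expected by chance. With library sizes left unscaled these were 2037 higher and 225 lower, and 0 passed after adjustment. DESeq2, with its own gene filter, called 229 genes at an adjusted p under 0.05, 58 higher and 171 lower, and limma voom called 0. The libraries of the groups did not overlap for 750 genes, 5.40% of those tested, where chance gives 1.59% on average. How far this share varies between regroupings of the libraries was not computed. Without MCF-10A EV replicate 4 the edgeR test called 2 genes, both lower: Cish at a log2 fold change of -2.78 and an adjusted p of 0.0214, and Stbd1 at -1.12 and an adjusted p of 0.00605.

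Cish, Rnf126, Vtcn1, Rxrg and Stbd1 had the smallest p among the genes lower in MDA-MB-231 EV, and none passed in edgeR. Cish (ENSMUSG00000032578; mm10, chromosome 9, 107296026 to 107302784, plus strand) was at 16.5, 11.2, 28.7 and 9.02 CPM (read counts scaled to library size) in MCF-10A EV replicates 1 to 4 and at 1.98, 2.08, 2.92, 4.03 and 2.80 CPM in MDA-MB-231 EV replicates 1 to 5. It was higher in all 4 MCF-10A EV libraries than in any of the 5 others, on 144 to 711 counts against 44 to 83. Its means were 16.3 ± 8.79 CPM (SD, n = 4) and 2.76 ± 0.825 CPM (SD, n = 5), a log2 fold change of -2.58 ± 0.34 (SE). Rnf126, a ubiquitin ligase, was at 127 ± 36.6 against 62.6 ± 4.86 CPM, a log2 fold change of -1.02 ± 0.17 (SE; edgeR adjusted p = 0.187). Vtcn1, which encodes the T-cell co-inhibitory ligand B7-H4, was low in both groups, at 2.81 ± 0.345 against 0.840 ± 0.334 CPM, with a log2 fold change of -1.73 ± 0.28. Rxrg, the retinoid X receptor gamma, had a log2 fold change of -0.62 ± 0.10 and Stbd1, a glycogen-binding protein, one of -0.95 ± 0.17. DESeq2 called Rnf126 (adjusted p = 3.99e-05), Rxrg (9.83e-05) and Stbd1 (0.000178), and gave no adjusted p for Cish and Vtcn1.

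Pdgfrl, Bgn, Ralb, Hspa2 and Trim47 had the smallest p among the genes higher in MDA-MB-231 EV, and none passed in edgeR (adjusted p from 0.187 to 0.247). Bgn, the matrix proteoglycan biglycan, was at 83.0 ± 15.9 CPM in MCF-10A EV and 151 ± 24.8 CPM in MDA-MB-231 EV, a log2 fold change of 0.86 ± 0.16 (SE), and DESeq2 called it (adjusted p = 0.000640). Pdgfrl had a log2 fold change of 0.79 ± 0.14, Hspa2, a chaperone of the Hsp70 family, one of 0.72 ± 0.15, Trim47 one of 0.62 ± 0.13 and Ralb, a Ras-like GTPase, one of 0.58 ± 0.12. DESeq2 also called Ralb (adjusted p = 0.00523) and Trim47 (0.00840). The CPM of these 10 genes is plotted per library.

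**Figure D1:**
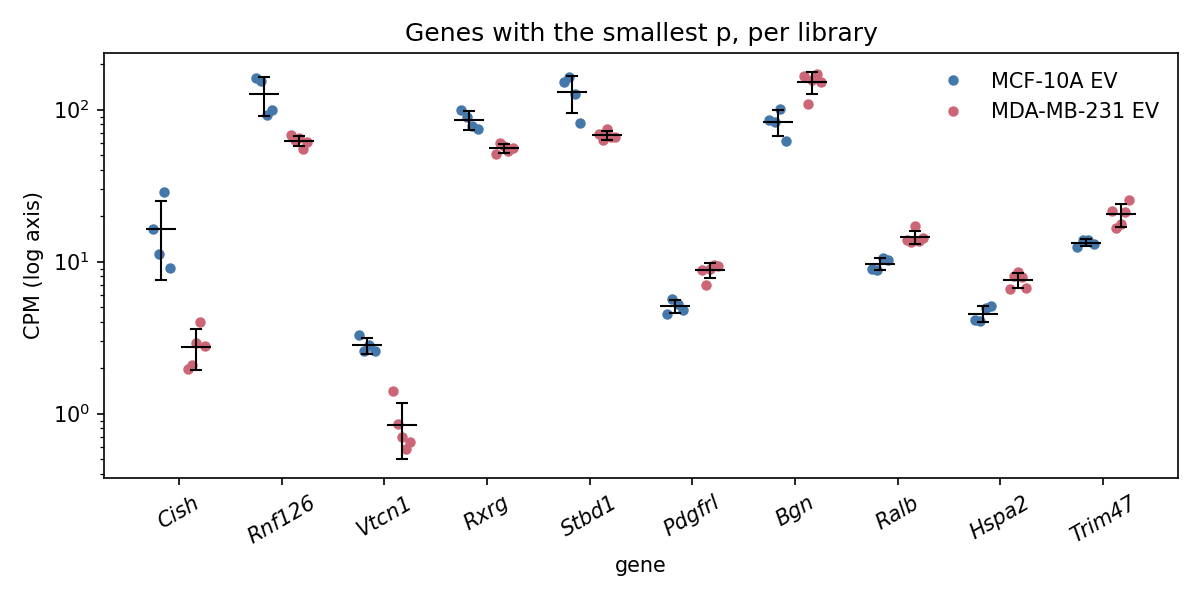
CPM (read counts scaled to library size, log axis) of the 5 genes with the smallest p in each direction. Points are libraries (4 MCF-10A EV, 5 MDA-MB-231 EV), and black bars the mean ± SD; Cish ranged from 9.02 to 28.7 CPM in MCF-10A EV and from 1.98 to 4.03 CPM in MDA-MB-231 EV.

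Of 43 gene lists, 40 had at least 5 tested members. With a preset correlation between genes of 0.01 (camera), 17 passed an adjusted p under 0.05, 11 higher and 6 lower in MDA-MB-231 EV. With the correlation estimated for each list 0 passed, the smallest adjusted p being 0.0871 for calcium release and uptake. In fry's direction test 1 list passed, again calcium release and uptake (adjusted p = 0.0128), and 9 passed in fry's test for change in either direction. A two-sided exact permutation test of each list's mean log2 CPM over 126 arrangements gave 8 lists an unadjusted p under 0.05 and 0 after adjustment. The smallest p that 126 arrangements allow is 0.00794. Calcium release and uptake and fast-fibre genes reached it and still had an adjusted permutation p of 0.159. The 0 after adjustment therefore says little against a list. No member of any list passed in edgeR over all genes tested, so the counts of members given with each list are those adjusted over the list alone. DESeq2 called some members, Ryr1, Myh4 and Sparc among them, and its calls are not given for every gene named. The median log2 fold change of all tested genes was 0.020, and 0.15 with library sizes left unscaled.

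Genes of calcium release and uptake, which couple the electrical signal of the fibre to contraction, fell as a list, with 26 of 32 members below 0 and 7 lower adjusted over the list alone (camera adjusted p = 3.95e-06; adjusted p = 0.0871 with an estimated correlation). Jph1, which holds the calcium store against the surface membrane, was at 582 ± 18.4 CPM in MCF-10A EV and 412 ± 25.9 CPM in MDA-MB-231 EV, a log2 fold change of -0.50 ± 0.093 (SE). Its adjusted p was 0.196 in edgeR and 1.84e-07 in DESeq2. The store's release channel Ryr1 had a log2 fold change of -0.40 ± 0.11, at 6788 ± 342 against 5134 ± 534 CPM, the voltage sensor Cacna1s one of -0.63 ± 0.20 (-0.35 without MCF-10A EV replicate 2) and Asph one of -0.54 ± 0.13. The list's mean log2 CPM was lower in each MDA-MB-231 EV library than in each MCF-10A EV library, with the smallest exact permutation p that the design allows (0.00794). The list passed camera's threshold without each library in turn, with medians from -0.28 to -0.21. With unscaled library sizes its median was -0.10, beside an all-gene median of 0.15. The heart isoform Ryr2 was near the detection limit, at 1.32 ± 0.717 against 1.61 ± 0.307 CPM, with a log2 fold change of 0.25 ± 0.38 that was -0.040 without MCF-10A EV replicate 2.

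Fast-fibre genes also fell as a list, with 14 of 15 members below 0 and 8 lower adjusted over the list alone (camera adjusted p = 6.74e-06; adjusted p = 0.471 with an estimated correlation). Myh4, the myosin heavy chain of the fastest fibres, was at 67144 ± 14183 CPM in MCF-10A EV and 40408 ± 7368 CPM in MDA-MB-231 EV, a log2 fold change of -0.73 ± 0.17 (SE). With unscaled library sizes the list's median was -0.20. Actn3 had a log2 fold change of -0.64 ± 0.19, Mybpc2 one of -0.62 ± 0.18 and Myoz1 one of -0.42 ± 0.14. Myh1 and Myh2, of intermediate fast fibres, had log2 fold changes of -0.23 ± 0.38 and 0.27 ± 0.45. Reads of near-identical myosin genes can be shared, so the values of Myh1, Myh2, Myh4 and Myh7 are uncertain. Myh1 turned to 0.28 without MCF-10A EV replicate 2 and to 0.14 on log2(FPKM + 1), and Myh2 to -0.066 without MCF-10A EV replicate 1.

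Slow-fibre genes rose as a list with the preset correlation, with 15 of 15 members above 0 and a median of 0.46 (camera adjusted p = 0.0117; adjusted p = 0.721 with an estimated correlation). This rested on MCF-10A EV replicate 1, whose mean log2 CPM over the list was 3.93, against 6.58 to 6.91 in the other MCF-10A EV libraries. Without that library the median was 0.076 and the adjusted p 0.968. Without MDA-MB-231 EV replicate 1 the median was 0.35 and the adjusted p 0.0756, and without MDA-MB-231 EV replicate 2 the median was 0.29. The slow myosin Myh7 had 504 counts in MCF-10A EV replicate 1, and its log2 fold change was 0.068 ± 0.91 (SE). Myl6b, Ankrd2, Csrp3 and Casq2 had log2 fold changes of 0.54, 1.12, 0.99 and 0.57, and 0 members were higher adjusted over the list alone. Ankrd2 was at 0.55 and Csrp3 at 0.47 without MDA-MB-231 EV replicate 1, and Casq2 at 0.28 without MCF-10A EV replicate 1. The fast-fibre list kept a median of -0.28 without MCF-10A EV replicate 1 (camera adjusted p = 4.01e-05).

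**Figure D2:**
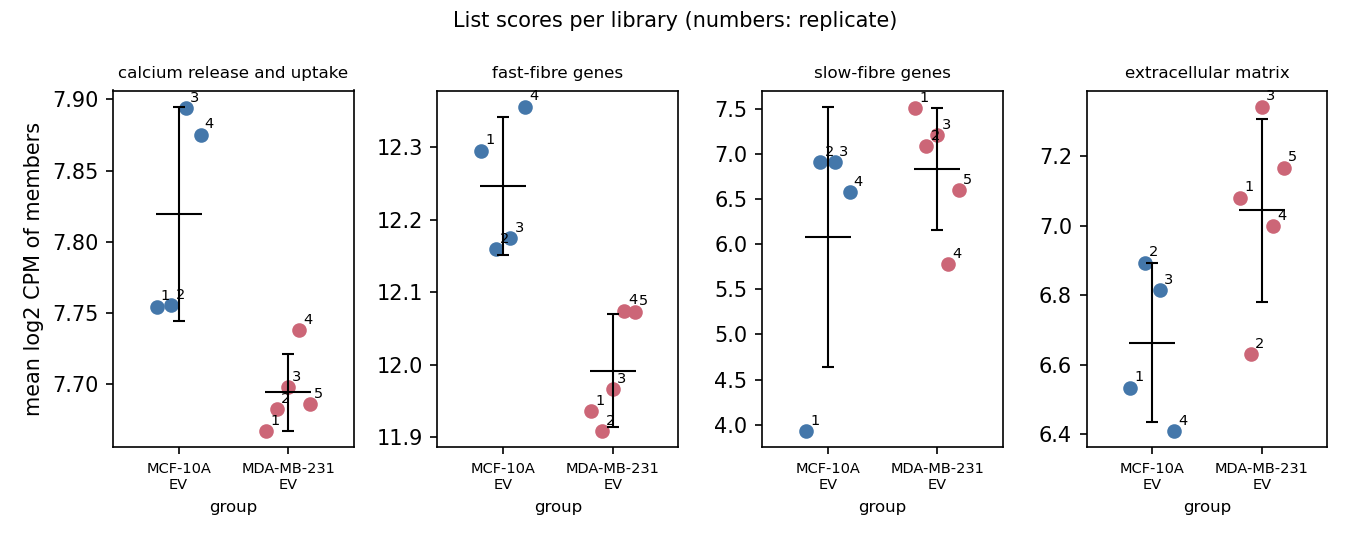
Mean log2 CPM over the members of 4 lists, per library; points carry the replicate number and black bars are the mean ± SD (4 MCF-10A EV, 5 MDA-MB-231 EV libraries). The vertical axes differ between panels and do not start at 0; the calcium and fast-fibre scores did not overlap between the groups, and MCF-10A EV replicate 1 had the lowest slow-fibre score, 3.93.

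Ribosomal proteins fell as a list by a small amount, with 69 of 73 members below 0, 0 lower adjusted over the list alone and a median of -0.16 (camera adjusted p = 6.88e-12; adjusted p = 0.471 with an estimated correlation). Rpl32, Rps15a, Rpl10a and Rpl13 had log2 fold changes of -0.49, -0.31, -0.30 and -0.29. Processed pseudogenes can share the reads of ribosomal protein genes, so these values are uncertain. Proteasome subunits, which degrade ubiquitin-tagged proteins, fell likewise, with 28 of 31 below 0, 0 lower adjusted over the list alone and a median of -0.15 (camera adjusted p = 5.20e-06; adjusted p = 0.471 with an estimated correlation). Psmd6, Psmd4, Psma3 and Psma4 had log2 fold changes of -0.35, -0.30, -0.24 and -0.23. Without both MCF-10A EV replicates 1 and 2 the proteasome median was -0.050 (camera adjusted p = 0.0295). With unscaled library sizes the medians were -0.024 for ribosomal proteins and -0.0092 for the proteasome, beside an all-gene median of 0.15.

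Ubiquitin ligases of muscle atrophy had a median of -0.11, with 15 of 18 members below 0 and 0 lower adjusted over the list alone (camera adjusted p = 0.0117; adjusted p = 0.471 with an estimated correlation). With unscaled library sizes the median was 0.029, beside an all-gene median of 0.15, so the list lay at -0.13 relative to all genes. Without MDA-MB-231 EV replicate 4 the adjusted p was 0.0517. Fbxo31 and Fbxo40 had log2 fold changes of -0.39 and -0.34, Fbxo21 one of 0.26 and Ubb one of -0.24; Ubb can share reads with other ubiquitin genes. Fbxo32 (atrogin-1) and Trim63 (MuRF1), the ligases most used as marks of muscle wasting, differed by less than their standard errors. Fbxo32 had a log2 fold change of 0.038 ± 0.17 (SE), at 262 ± 51.8 against 269 ± 59.3 CPM, which was -0.085 without MDA-MB-231 EV replicate 1. Trim63 had one of -0.051 ± 0.16 (SE), which was 0.085 with unscaled library sizes, below the all-gene median of 0.15.

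Genes of glycolysis and glycogen fell as a list with a median of -0.18, 17 of 30 members below 0 and 0 lower adjusted over the list alone (camera adjusted p = 0.0132; adjusted p = 0.574 with an estimated correlation). The muscle glycogen phosphorylase Pygm had a log2 fold change of -0.40 ± 0.14, Eno3 one of -0.40 ± 0.14 and Ppp1r3c one of -0.71 ± 0.22 (SE). Pkm, the pyruvate kinase of muscle, had -0.21 ± 0.14 and the glycogen synthase Gys1 0.036 ± 0.12. The list lost its call without MCF-10A EV replicate 1 (adjusted p = 0.0526, median -0.10) and without MCF-10A EV replicate 2 (adjusted p = 0.0602), and its median was -0.28 without MDA-MB-231 EV replicate 4 and -0.044 with unscaled library sizes (all genes 0.15). Fatty acid oxidation rose as a list, with 24 of 27 members above 0, 0 higher adjusted over the list alone and a median of 0.31 (camera adjusted p = 0.000445; adjusted p = 0.603 with an estimated correlation). Hadhb, Cpt2, Echs1 and Hadh had log2 fold changes of 0.46, 0.37, 0.34 and 0.34. Without MCF-10A EV replicate 1 the median was 0.18 and the adjusted p 0.119, and without MDA-MB-231 EV replicate 2 the median was 0.19.

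Extracellular matrix genes rose as a list, with 30 of 31 members above 0, 3 higher adjusted over the list alone and a median of 0.33 (camera adjusted p = 1.03e-06; adjusted p = 0.471 with an estimated correlation). Besides Bgn, Sparc had a log2 fold change of 0.87 ± 0.19 (SE; 592 ± 160.0 against 1082 ± 183 CPM), Lum one of 0.52 ± 0.14 and Postn one of 0.47 ± 0.15. Markers of fibroblasts and fibro-adipogenic progenitors, which make matrix, rose with them, with 15 of 19 above 0, 3 higher adjusted over the list alone and a median of 0.25 (camera adjusted p = 0.000202; adjusted p = 0.471 with an estimated correlation). Mfap4 had a log2 fold change of 1.27 ± 0.28, Fbln1 one of 0.58 ± 0.14 and Serpinf1 one of 0.62 ± 0.21. Lum is a member of both lists, so they are not independent. Without MCF-10A EV replicate 2 the median of the fibroblast list was 0.15.

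Tendon genes rose as a list, with 13 of 15 members above 0, 5 higher adjusted over the list alone and a median of 0.37 (camera adjusted p = 0.000202; adjusted p = 0.574 with an estimated correlation). Fmod had a log2 fold change of 0.90 ± 0.20, Comp one of 1.21 ± 0.35, Prg4 one of 1.05 ± 0.31 and Tnmd one of 0.87 ± 0.24. The median was 0.22 without MCF-10A EV replicate 1 and 0.89 without MCF-10A EV replicate 2. Among the 5 libraries that also held transcripts of pancreatic islets, the tendon median was -0.074 (camera adjusted p = 0.455), and among the 4 without them 1.11 (1.43e-08). The 5 were MCF-10A EV replicates 2 and 3 and MDA-MB-231 EV replicates 1, 3 and 4. The tendon list's mean log2 CPM was 5.55 and 5.32 in MCF-10A EV replicates 2 and 3, against 3.96 and 4.80 in replicates 1 and 4. It was 5.35 to 5.59 in MDA-MB-231 EV. So few mice cannot tie a difference between these subsets, in this or other lists, to islet transcripts. Bone and cartilage genes rose as a list, with 9 of 10 members above 0, 0 higher adjusted over the list alone and a median of 0.82 (camera adjusted p = 0.00695; adjusted p = 0.471 with an estimated correlation). Without MCF-10A EV replicate 4 their median was 0.65 and the camera adjusted p 0.0690, and on log2(FPKM + 1) the median was 0.32. Spp1, Cytl1 and Col2a1 had log2 fold changes of 0.97, 1.19 and 0.89, and Col9a1 one of -0.97.

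Markers of endothelium, the lining of blood vessels, rose as a list, with 18 of 20 above 0, 3 higher adjusted over the list alone and a median of 0.36 (camera adjusted p = 2.03e-05; adjusted p = 0.471 with an estimated correlation). Pecam1 had a log2 fold change of 0.36 ± 0.10, Cav1 one of 0.36 ± 0.10, Vwf one of 0.60 ± 0.17 and Esam one of 0.42 ± 0.14. Mast cell markers rose as a list, with 8 of 8 above 0, 6 higher adjusted over the list alone and a median of 0.86 (camera adjusted p = 0.000169; adjusted p = 0.471 with an estimated correlation). The mast cell proteases Mcpt4, Cma1 and Cpa3 had log2 fold changes of 1.39, 1.11 and 0.77, and the receptor Kit one of 0.77. Mast cell transcripts were few, with Cpa3 at 4.24 ± 1.01 against 7.28 ± 2.38 CPM. The list's mean log2 CPM was 0.96 in MCF-10A EV replicate 2, against 2.11 to 2.12 in the other MCF-10A EV libraries. Schwann cell and nerve genes rose as a list, with 15 of 16 above 0, 0 higher adjusted over the list alone and a median of 0.46 (camera adjusted p = 0.00344; adjusted p = 0.603 with an estimated correlation). Mbp, Pmp22, S100b and Ncmap had log2 fold changes of 0.77, 0.63, 0.57 and 0.45; without MDA-MB-231 EV replicate 4, Mbp was at 0.46, Pmp22 at 0.38 and Ncmap at 0.22. The camera adjusted p of the Schwann list was 0.0602 without MCF-10A EV replicate 2, 0.0545 without MCF-10A EV replicate 3 (median 0.28) and 0.0517 without MDA-MB-231 EV replicate 4 (median 0.22). Its median was 0.83 in the 5 libraries with islet transcripts (camera adjusted p = 0.000174) and 0.087 in the 4 without (0.816). The Schwann list's mean log2 CPM was lowest, at 2.01, in MCF-10A EV replicate 2. That library also had the fewest brain transcripts, 4.12 CPM against 91.6 to 200.2 CPM in the others. Whether brain transcripts add to the list was not tested.

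Cell cycle genes rose as a list, with 16 of 19 members above 0, 2 higher adjusted over the list alone and a median of 0.84 (camera adjusted p = 3.95e-06; adjusted p = 0.471 with an estimated correlation). Their transcripts were rare: Top2a was at 0.497 ± 0.448 against 2.35 ± 1.66 CPM (log2 fold change 2.20 ± 0.63 SE) and Rrm2 at 0.802 ± 0.186 against 1.84 ± 0.613 CPM (1.20 ± 0.33 SE). Mki67 had a log2 fold change of 1.48 ± 0.54 and Mcm3 one of 0.44 ± 0.15. The median was 0.56 without MDA-MB-231 EV replicate 5, and 0.26 on log2(FPKM + 1), which shrinks changes of rare transcripts. Immediate early genes, which cells switch on within minutes of a stimulus, rose as a list, with 24 of 25 members above 0, 0 higher adjusted over the list alone and a median of 0.45 (camera adjusted p = 0.000759; adjusted p = 0.574 with an estimated correlation). Nr4a2, Fos, Cyr61 and Ier3 had log2 fold changes of 1.39, 1.28, 0.90 and 0.63, Nr4a2 being at 0.85 without MDA-MB-231 EV replicate 4. The list's median was 0.27 without MCF-10A EV replicate 1. Its call was lost without both MCF-10A EV replicates 1 and 2 (median 0.069, camera adjusted p = 0.964) and in the 4 libraries without islet transcripts (median 0.36, adjusted p = 0.0601).

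**Figure D3:**
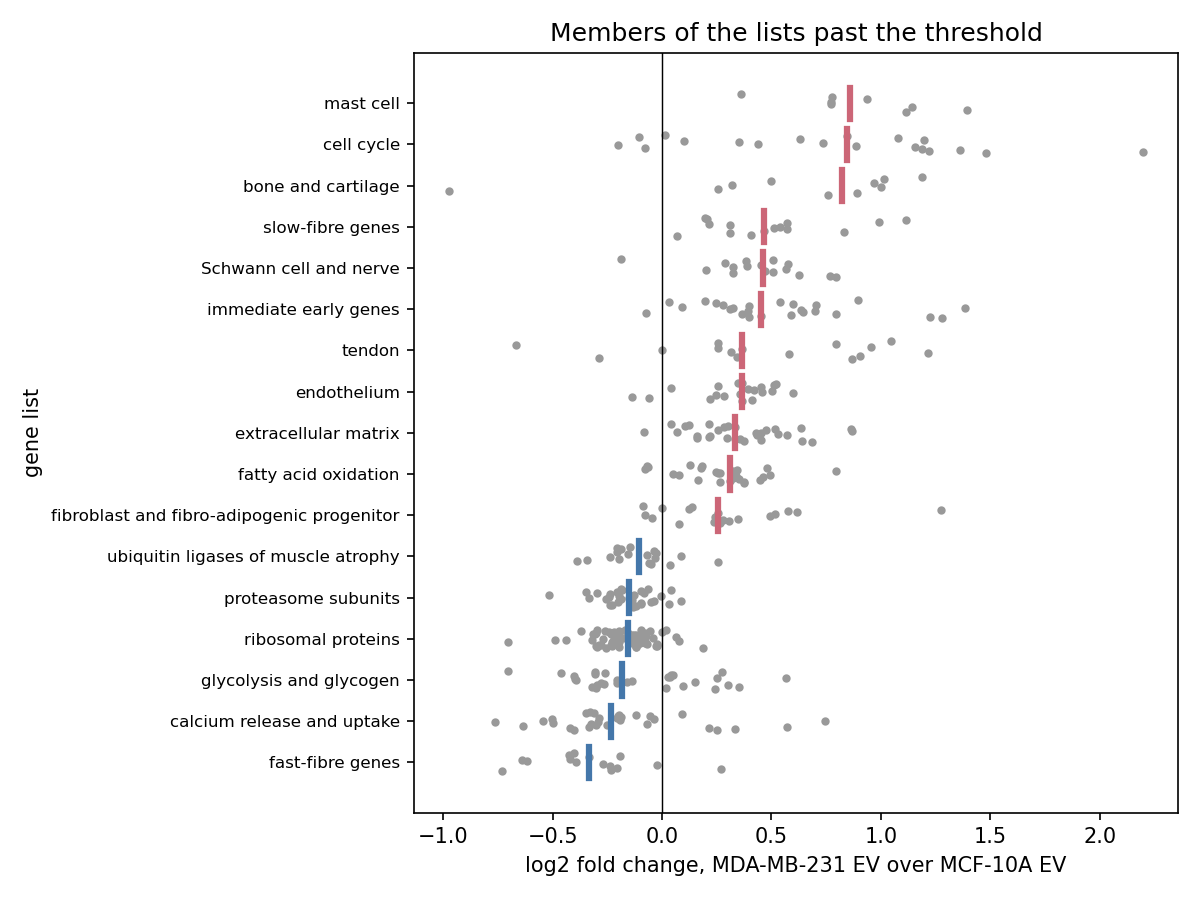
Log2 fold change (MDA-MB-231 EV over MCF-10A EV, 5 against 4 libraries) of each tested member of the 17 lists past the camera threshold with a preset correlation. Grey points are genes and coloured bars list medians, from -0.33 for fast-fibre genes to 0.86 for mast cell markers; 0 lists passed with an estimated correlation, and with unscaled library sizes the ubiquitin ligase median was 0.029 and the all-gene median 0.15.

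Genes of growth and sugar handling did not pass in edgeR. Myostatin (Mstn), which restrains muscle growth, was at 85.0 ± 21.9 CPM in MCF-10A EV and 45.1 ± 12.96 CPM in MDA-MB-231 EV, a log2 fold change of -0.91 ± 0.22 (SE). Its adjusted p was 0.252 in edgeR and 0.0106 in DESeq2. Igf1 had a log2 fold change of -0.061 ± 0.40, which was 0.55 without MCF-10A EV replicate 2 and 0.088 with unscaled library sizes, below the all-gene median of 0.15. Ogt and Oga (Mgea5), the enzymes that add and remove O-linked N-acetylglucosamine, had log2 fold changes of -0.17 ± 0.15 and -0.23 ± 0.12. The calpains Capn1, Capn2 and Capn3 had -0.21 ± 0.10, -0.23 ± 0.12 and -0.21 ± 0.10, all SE. The glucose transporter Slc2a4 had 0.026 ± 0.10 and Ppargc1a, a regulator of mitochondrial genes, -0.50 ± 0.32, which was 0.00090 without MCF-10A EV replicate 2.

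The remaining 23 tested lists did not pass with the preset correlation. Circadian clock and output genes had a median of -0.052 (adjusted p = 0.0543) and macrophage markers one of 0.20 (0.0815). These calls changed with the libraries used: the circadian list passed in 4 of the 9 fits without 1 library, and macrophage markers in 2, with a median of 0.44 and an adjusted p of 4.01e-05 without MCF-10A EV replicate 1. Among mitochondrial and metabolic lists, the median was 0.083 (0.102) for nuclear-encoded OXPHOS, 0.094 (0.698) for the mitochondrial genome, 0.014 (0.893) for the TCA cycle and 0.16 (0.960) for fatty acid and cholesterol synthesis. For calpains it was -0.073 (0.384), for hexosamine and O-GlcNAc genes 0.021 (0.960), for autophagy and lysosome -0.011 (0.546), for growth signalling -0.042 (0.371) and for reported miR-122 targets 0.012 (0.714). Myogenesis and regeneration had 0.18 (0.597), denervation and neuromuscular junction -0.0032 (0.790) and satellite cells 0.11 (0.790). Among stress and signalling lists, oxidative stress had 0.11 (0.102), heat-shock proteins 0.14 (0.233), the unfolded protein response -0.017 (0.886), glucocorticoid response -0.0014 (0.950), inflammatory signalling 0.11 (0.177) and interferon response 0.070 (0.177). Adipocytes had a median of 0.54 (0.171), pericytes and smooth muscle 0.25 (0.125) and erythroid cells -0.22 (0.403). Adipocyte genes passed in opposite directions in the subsets by islet transcripts, with a median of 1.249 (0.00166) in the 5 libraries with them and -0.33 (0.00776) in the 4 without. The median and the direction of the camera test differed in sign for hexosamine, denervation and miR-122 target genes. Lymphocyte, neutrophil and skin markers had 2, 4 and 4 tested members, too few for the test, with medians of -0.30, -0.32 and -0.027.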

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

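The tests of fewer slow fibres and of a lower share of muscle fibres were chosen only after the result was seen. In 20 of 282 groups of values (7.09%), 1 library lay far from the others of its group by Dixon's ratio, and chance flags about 1 in 20 groups.

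Among genes, in log2 CPM, MDA-MB-231 EV replicate 2 lay apart for Pdgfrl (2.83, others 3.17 to 3.27), Bgn (6.77, others 7.25 to 7.43), Rpl32 (7.40, others 7.11 to 7.17) and Hadh (7.88, others 7.44 to 7.50). MDA-MB-231 EV replicate 3 lay apart for Ralb (4.10, others 3.76 to 3.85), and MDA-MB-231 EV replicate 1 for Fbxo40 (8.80, others 8.37 to 8.46) and S100b (0.87, others 1.90 to 2.10). MCF-10A EV replicate 1 lay apart for Tnmd (3.06, others 4.39 to 4.55) and Myoz1 (11.37, others 10.91 to 10.98), and MCF-10A EV replicate 2 for Mcpt4 (0.58, others 2.60 to 3.003). Among lists, in mean log2 CPM, MCF-10A EV replicate 1 lay apart for hexosamine genes (3.44, others 3.30 to 3.32) and slow-fibre genes (3.93, others 6.58 to 6.91), and MCF-10A EV replicate 2 for oxidative stress (4.84, others 5.16 to 5.22) and mast cell markers (0.96, others 2.11 to 2.12). MDA-MB-231 EV replicate 4 lay apart for glycolysis (8.68, others 8.50 to 8.55) and satellite cell markers (3.95, others 4.25 to 4.35), replicate 1 for the unfolded protein response (5.34, others 5.02 to 5.10) and replicate 2 for miR-122 targets (6.18, others 6.30 to 6.34). Total counts, in units of 1e6, were 24.2 in MDA-MB-231 EV replicate 1, against 19.5 to 20.4 in its group.

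MCF-10A EV replicate 2 scored 81.1 on the first principal component, which held 39.9% of the variance, against -12.7 to -5.87 in the other MCF-10A EV libraries. It was also the shallowest library, with 4.12 CPM of brain transcripts against 91.6 to 200.2 CPM in the others, and 377 counts of the liver gene Alb, named after its values were seen, against 0 to 25. Its sum over the liver set was within the range of the others, but that sum includes Hp and Cyp2e1, which every library expressed. With every library thinned to its depth, Dixon's ratio on that component was 0.917, against 0.927 before, which argues against depth. With each library's trend over transcript length and GC content removed, its median absolute log2 deviation was 0.365, still 1.59 times the highest of the others, which argues against that trend as the whole cause. Nothing in the design sets this mouse apart, so no biological explanation was tested, and a difference in dissection or library preparation stays open.

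With a preset correlation, though not with an estimated one (adjusted p 0.471 and 0.721), fast-fibre genes were lower and slow-fibre genes higher as lists in MDA-MB-231 EV, and MCF-10A EV replicate 1 had few slow-fibre transcripts. Without that library the slow-fibre median was 0.076, so the higher slow-fibre list may come from the piece of muscle sampled in that mouse. The fast-fibre median stayed at -0.28, which argues against the same cause for the fast-fibre list. A lower share of muscle fibres in the tissue cannot be told apart: 20 genes of all fibre types had a median of -0.17 (exact permutation p = 0.0873, two-sided), between no change and that of the fast-fibre list, and the same stays open for the calcium list (median -0.23). The EVs injected, the difference the design names, stay open as a biological explanation.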

How the results depend on the processing

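Of the tests reported here, leaving out both MCF-10A EV replicates 1 and 2, sample weights, the covariates, the subsets by islet transcripts and the permutation of list scores were chosen only after the result was seen. The edgeR count of 0 genes at an adjusted p under 0.05 (1781 at an unadjusted p under 0.05, of 13901 tested) became 229 with DESeq2, 58 higher and 171 lower. DESeq2 gave an unadjusted p to 21832 genes, but its own filter left fewer of them to adjust over, and Cish and Vtcn1 got no adjusted p. The edgeR count was 0 to 2 without each library in turn, the 2 being lower genes without MCF-10A EV replicate 4. It was 0 under every other alternative run, edgeR without a count filter (21860 genes) included, with 1731 genes at an unadjusted p under 0.05 in limma voom. That unadjusted count was 1326 to 2089 without each library in turn, 738 in the 5 libraries with islet transcripts and 1133 in the 4 without. The count of 17 lists became 0 with an estimated correlation and 1 with fry, and was 16 to 20 without each library in turn. It was 0 by exact permutation, where lists at the smallest possible p (0.00794) had an adjusted permutation p of 0.159. The cause of these changes was not tested.

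With the replicate block (8 libraries), 0 genes passed, 1007 had an unadjusted p under 0.05 and 21 lists passed. Same-numbered libraries correlated at -0.30, -0.18, 0.038 and 0.080, and none correlated best with its own number. These values give no sign of a pairing, but they cannot exclude a shared litter, cage or day, which the labels do not state. Under the block the sign turned for Myh1 (0.091), Igf1 (0.13), autophagy (0.012), denervation (0.040), growth signalling (0.029), unfolded protein response (0.0019), glucocorticoid response (0.0065) and miR-122 targets (-0.0074).

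Of named genes' values under alternatives, 2427 kept direction and side of the threshold, 31 passed it newly and 49 turned sign; for lists these were 591, 33 and 61, with 75 no longer past it. Of the lists that turned sign among these 61, tendon and slow-fibre genes had passed in the main test. Of the other scalings, only RLE factors were counted there for lists. With unscaled library sizes the ubiquitin ligase list, which had passed too, had a median of 0.029, beside an all-gene median of 0.15. The sign turned with unscaled library sizes for Trim63 (0.085) and Igf1 (0.088), on log2(FPKM + 1) for Myh1 (0.14), Trim63 (0.055) and Igf1 (0.18), on log2(FPKM + 0.1) for Myh1 (0.14), Trim63 (0.056) and Igf1 (0.25), with voom for Igf1 (0.15) and with voom sample weights for Myh1 (0.19) and Igf1 (0.46). With the islet covariate it turned for denervation (0.0053) and glucocorticoid response (0.0042), and with the slow-fibre covariate for Gys1 (-0.0093), Slc2a4 (-0.010), Fbxo32 (-0.029), Myh7 (-0.69), TCA cycle (-0.022), slow-fibre genes (-0.0024), denervation (0.037), miR-122 targets (-0.048) and satellite cell (-0.029). Without both MCF-10A EV replicates 1 and 2 it turned for Fbxo32 (-0.024), Igf1 (0.66), OXPHOS (-0.076), TCA cycle (-0.010), growth signalling (0.023), unfolded protein response (0.12), miR-122 targets (-0.0054) and erythroid (0.51). In libraries with islet transcripts it turned for Pkm (0.020), Myh2 (-0.17), Gys1 (-0.059), Myh7 (-0.57), TCA cycle (-0.013), denervation (0.045), glucocorticoid response (0.27), miR-122 targets (-0.059), tendon (-0.074) and satellite cell (-0.015), and in those without for Ppargc1a (0.18), Ryr2 (-0.091), Myh1 (0.22), Trim63 (0.015), Fbxo32 (-0.13), Igf1 (0.45), fatty acid synthesis (-0.21), unfolded protein response (0.0047), adipocyte (-0.33) and macrophage (-0.020). For all these the cause was not tested.

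Leaving out each library in turn changed the sign of some values, with these ranges: Ppargc1a -0.69 to 0.00090, Ryr2 -0.040 to 0.48, Myh1 -0.51 to 0.28, Myh2 -0.066 to 0.65, Trim63 -0.20 to 0.029, Gys1 -0.022 to 0.15, Slc2a4 -0.027 to 0.057 and Fbxo32 -0.085 to 0.18. Other ranges were Igf1 -0.29 to 0.55, Myh7 -0.33 to 0.85, autophagy -0.034 to 0.018, hexosamine -0.045 to 0.078, OXPHOS -0.0062 to 0.19, mitochondrial genome -0.011 to 0.20, TCA cycle -0.036 to 0.094 and fatty acid synthesis -0.057 to 0.21. Further ranges were denervation -0.067 to 0.072, interferon response -0.021 to 0.20, unfolded protein response -0.10 to 0.10, glucocorticoid response -0.093 to 0.28, miR-122 targets -0.036 to 0.072, adipocyte -0.071 to 0.90 and erythroid -0.40 to 0.28. Without a change of sign, some values still moved by over 1.5 times: Mki67 1.22 to 2.22, Col9a1 -1.21 to -0.65, Col2a1 0.67 to 1.45, Fbxo40 -0.43 to -0.19, Cyr61 0.66 to 1.43, Ier3 0.42 to 0.96, Capn3 -0.27 to -0.13, Pkm -0.29 to -0.096 and Ogt -0.27 to -0.041. Among lists that had not passed, these were calpains -0.18 to -0.026, heat-shock proteins 0.045 to 0.20, inflammatory signalling 0.038 to 0.20, satellite cell 0.032 to 0.21, myogenesis 0.078 to 0.31, growth signalling -0.045 to -0.014, circadian genes -0.11 to -0.013, macrophage 0.047 to 0.44 and pericyte 0.17 to 0.29. Rare transcripts rest on few counts: Ryr2 had 4 in MCF-10A EV replicate 2, against 26 to 41 in the others, and Rrm2 had 10 in MCF-10A EV replicate 1.

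Calls of lists past the camera threshold were also lost in the following fits, given with adjusted p. With the slow-fibre covariate these were glycolysis (0.0795), fatty acid oxidation (0.176) and slow-fibre genes themselves (0.578). Without both MCF-10A EV replicates 1 and 2 they were ubiquitin ligases (0.125), glycolysis (0.274), fatty acid oxidation (0.171), slow-fibre genes (0.738) and immediate early genes (0.964). In libraries with islet transcripts they were ubiquitin ligases (0.0546), glycolysis (0.455), fatty acid oxidation (0.152), slow-fibre genes (0.821), tendon (0.455) and bone and cartilage (0.123), and in those without, ubiquitin ligases (0.0710), immediate early genes (0.0601) and the Schwann list (0.816). Of lists that had not passed, some did so in fits without 1 library: circadian genes in 4 of 9, OXPHOS in 3, macrophage, adipocyte and pericyte markers in 2 each, and interferon response and oxidative stress in 1 each. Without both MCF-10A EV replicates 1 and 2, such passes were OXPHOS (lower, 0.00827), glucocorticoid response (lower, 0.00583), circadian genes (lower, 0.00583), interferon response (higher, 5.88e-06), macrophage (higher, 0.000284) and pericyte (higher, 0.0385). In libraries with islet transcripts they were OXPHOS (higher, 0.00125), oxidative stress (higher, 0.0191), circadian genes (lower, 0.0153), adipocyte (higher, 0.00166) and macrophage (higher, 0.00126), and in those without, fatty acid synthesis (lower, 0.00142) and adipocyte (lower, 0.00776). With the slow-fibre covariate they were interferon response (higher, 0.00904), adipocyte (higher, 0.000423) and macrophage (higher, 0.00252), and with the islet covariate OXPHOS (higher, 0.0295). Some lists kept their call while the median moved by about 1.5 times or more. Without both MCF-10A EV replicates 1 and 2 these were the proteasome (-0.050), endothelium (0.23) and tendon (0.55). In libraries with islet transcripts they were ribosomal proteins (-0.092), the Schwann list (0.83) and fibroblast genes (0.38). In those without, they were ribosomal proteins (-0.24), glycolysis (-0.31), slow-fibre (1.03), tendon (1.11), mast cell (0.57) and fibroblast genes (0.15). With the slow-fibre covariate it was the Schwann list (0.72).

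List medians also moved with the scaling, as did the median of all genes, which was 0.020, 0.15 with unscaled library sizes and 0.099 on log2(FPKM + 1). With unscaled library sizes the medians were -0.10 for calcium, -0.20 for fast-fibre, -0.044 for glycolysis and 0.39 for fibroblast genes. They turned sign for calpains (0.069), autophagy (0.12), denervation (0.13), growth signalling (0.094), unfolded protein response (0.12), glucocorticoid response (0.13) and circadian genes (0.082). On log2(FPKM + 1) they were -0.077 for calcium, -0.20 for fast-fibre, -0.043 for glycolysis, 0.74 for slow-fibre, 0.59 for tendon, 0.26 for cell cycle and 0.32 for bone and cartilage genes, the last 2 moving against the median of all genes. With the 20 most abundant genes left out, the mitochondrial genome was at 0.00060. On log2(FPKM + 0.1) cell cycle genes were at 0.74 and bone and cartilage genes at 0.72.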

Other observations

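The tests of pancreatic tissue and of STAT5 signalling were chosen only after the result was seen, and the gene sets for islet, acinar, brain, liver and STAT5 genes were written then too.

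Insulin transcripts were present in 5 of the 9 libraries, of both groups: Ins2 had 5, 639, 1873 and 7 counts in MCF-10A EV replicates 1 to 4 and 2322, 5, 1309, 914 and 6 in MDA-MB-231 EV replicates 1 to 5. Acinar enzymes, which dominate pancreas RNA, had 0.00784 times the summed counts of islet genes in those 5 libraries, which argues against pancreatic tissue; the islet sum includes Mafa, which all 9 libraries expressed. Of 12 other islet genes, 50% (6: Ins1, Iapp, Sst, G6pc2, Chga and Scg2) were higher in all 5 libraries than in the 4 others, neither above nor below the bounds set. Among those not separated, Mafa had 1195 to 2896 counts and Abcc8 57 to 163 over all 9 libraries. The share thus depends on the genes listed and cannot decide, and carry-over from libraries of isolated islets stays open as a candidate source. The genes named here were chosen after their values were seen.

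Transcripts of brain genes such as Snap25 and Slc17a7, named after their values were seen, summed to 91.6 to 200.2 CPM in 8 libraries and to 4.12 CPM in MCF-10A EV replicate 2. Over the liver set that library's sum did not stand out, with 74.4 CPM against 18.5 to 113.8 CPM. That sum includes Hp (45 to 774 counts) and Cyp2e1 (183 to 1284), which every library expressed. Their raw counts, not scaled to library size, were lowest in MCF-10A EV replicate 2, which was also the shallowest library. That library held most counts of some other liver genes, likewise named after their values were seen: Alb had 377 counts there against 0 to 25 elsewhere, Serpina3k 29 against 0, and Cps1 and Fga 26 each against 0 to 1. The cause of these differences was not tested.

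Because STAT5 induces Cish, lower STAT5 signalling was considered for its low level in MDA-MB-231 EV. The median log2 fold change of 8 other STAT5-related genes was 0.053, with members going both ways: Socs2 was at -0.87 and Ghr at -0.37, but Pim1 at 0.18. Under the bound first written, this result counted against the hypothesis. The bound was changed after the median was seen, so the changed bound cannot decide the question. Stat5b itself, looked at only afterwards, had a log2 fold change of -0.42 in DESeq2 (DESeq2 adjusted p = 0.0288, edgeR adjusted p = 0.260). The hypothesis was thus not decided: the median of the set went against it, while Socs2, Ghr and Stat5b were lower.

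In regroupings of the 9 libraries, 100 of 100 gave at least the real edgeR count of 0 genes (highest other 8), which every grouping must, so this comparison decides nothing. For genes at an unadjusted p under 0.05, 1 of 100, the real grouping itself, reached 1781 (highest other 1568, median 507). This argues against chance for that count without excluding it, since not all 126 groupings were drawn. For DESeq2, 1 of 30, again the real grouping, reached 229 genes (highest other 58), and 20 of the 30, the real one included, called at least 1 gene. The other groupings of the 126, the one with 1568 genes in edgeR among them, were not run with DESeq2. The count thus argues against chance without excluding it. For lists, 10 of 100 gave 17 or more (highest other 22, median 12), so chance was not excluded for the number of lists past the preset-correlation test.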
